A study of Mus musculus with 4 samples.

How the data were processed

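Visium sections of fresh-frozen mouse liver were processed by the authors with Space Ranger 1.2.2, per the file headers, on the mm10 genome, as the submitters' processing notes also state. The deposited matrices hold counts: each value is the number of UMIs of 1 gene in 1 spot, whole numbers without scaling, for 31253 features, of which 91 share a gene symbol with another feature and were kept apart by their identifiers. The barcodes are those of the filtered matrix. Spot positions were not used here, so no distances between spots were computed.

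Each of the 4 sections was taken as 1 sample, with the 2 MAFL sections against the 2 MASH sections as the labels give them. Spots with fewer than 500 UMIs were left out, 3 in MAFL-1 and 3 in MASH-1. The kept spots held 32249289, 38126800, 63808230 and 44581221 UMIs in MAFL-1, MAFL-2, MASH-1 and MASH-2, so a gene with 3 UMIs or fewer in a section is near the floor. Counting error is small at this depth: a chi-square of the counts of 2 replicate sections, per degree of freedom, came to 67.7 for MAFL and 116 for MASH over genes with at least 50 UMIs in both sections together. Differences between sections of a group thus far exceed counting error, which is all that the printed intervals cover.

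Counts were summed over all kept spots of a section, or over the spots of a class within a section, and fitted with edgeR 4.0.16 (TMM, filterByExpr, robust quasi-likelihood fit, Benjamini-Hochberg adjusted p of 0.05) in R 4.3.3, with limma 3.58.1 and DESeq2 1.42.0 beside it. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 did the rest. Comparisons of spot classes had the section as a block, and their difference between the groups was tested as an interaction. The zone score of a spot was the log2 ratio of the summed UMIs of 6 periportal hepatocyte genes (Cyp2f2, Hal, Sds, Hsd17b13, Pck1, Gls2) to those of 6 pericentral ones (Cyp2e1, Glul, Oat, Gulo, Cyp1a2, Slc1a2), each sum plus 1, and the top and bottom of 3 equal classes per section were called periportal and pericentral. LAM-gene-high and LAM-gene-low spots were the top 10% and the bottom 50% by the share of 13 genes (Trem2, Gpnmb, Spp1, Cd9, Lgals3, Fabp5, Cd63, Lpl, Mmp12, Itgax, Atp6v0d2, Capg, Lilrb4a), ranked within 5 bins of total UMIs of each section. Thrsp-high and Thrsp-low spots were the top and bottom of 3 classes ranked in the same bins. Ties in these rankings were broken at random. Genes that defined a class were left out of that class's test. A spot holds several cells, so no spot was given a cell type. For shares of spots with a UMI and for Spearman correlations, each spot was thinned at random (seed 20240517) to 5000 UMIs, which at least 98.3% of the spots of every section reached.

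Gene lists of cell types, pathways and liver functions, 40 in all with 574 symbols, the classes, the tests and 100 alternatives were fixed before the data were examined. Of the symbols 571 were found, and Mx1, Ddit3 and Atp5o are not analysed here. Lists with at least 3 tested genes were tested with camera on log2 CPM (prior count 2, preset correlation 0.01), again with an estimated correlation, and with fry. A gene may stand in several lists. The genes named were the 10 highest and 10 lowest log2 fold changes for whole sections and the 5 highest and 5 lowest for each other comparison, among genes past 0.05 with a mean of at least 20 CPM and the same direction in every section. Predicted genes and Mup, ribosomal, mitochondrial, haemoglobin and sex-linked genes were left out of this rule. The 8 genes of the title and of the LAM field were named in every comparison, with up to 4 members of the smallest p of each list described. Members named from counts adjusted over a list alone, or because an alternative reversed or ended their call, were chosen after their values were seen. Single values of 2 list members are not reported here, and both genes stayed in the tests of their lists.

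The fits were tested on simulated data drawn from the means, dispersions and library sizes of the real counts, 1 set for each of 5 comparisons, with 200 genes changed. For whole sections edgeR recovered 51 of 100 genes changed 2-fold and 87 of 100 changed 4-fold, and 26 of 164 calls (15.9%) were false. For zones 94 and 96 of 100 were recovered with 24 of 214 calls false (11.2%), for LAM spots 91 and 97 with 21 of 209 (10.0%), for Thrsp spots 98 and 98 with 13 of 209 (6.22%), and for the zone interaction 60 and 89 with 3 of 152 (1.97%). In these single sets the share of false calls was above the nominal 5% in 4 of these 5 comparisons and below it in the zone interaction. With 1 set each, a share near 5% is not told apart from it. The real zone and LAM-spot fits called 2463 and 2427 genes, far more than the 200 changed here, so these shares do not carry over to those counts. The comparisons of the groups within zones and the LAM-spot interaction were not simulated.

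The alternatives were DESeq2, other size factors, library totals alone, no filter or a stricter filter on low counts, no minimum or 2000 UMIs per spot, leaving out mitochondrial, haemoglobin and Mup genes, each section left out, sections of the same number as a block, other definitions of the zone score, of the classes and of the LAM list, and other depths of thinning. A further 8 were added after the data were seen. Scaling by library totals moved the median log2 fold change by 0.102 for whole sections, 0.134 for pericentral spots and 0.133 for LAM spots, so changes are relative to the TMM scale.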

Results

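Spatial transcriptomes of mouse liver were recorded with 10x Visium, in which each spot of a slide captures the RNA of several neighbouring cells. The 4 sections came from 2 groups on a diet labelled WD: MAFL after 8 weeks (sections MAFL-1 and MAFL-2) and MASH after 16 weeks (sections MASH-1 and MASH-2). The title of the series concerns the cytokine Mif, hepatocytes positive for the lipogenic gene Thrsp, Cd74-positive lipid-associated macrophages (LAM) and the periportal zone of the liver lobule, so the comparisons were made between the groups, between lobule zones and between spots rich and poor in LAM genes or in Thrsp. The sections held 2036, 1881, 2467 and 1862 spots (MAFL-1, MAFL-2, MASH-1, MASH-2), with a median of 15430.5, 19671, 25291 and 20132.5 UMIs and of 3204.5, 3605, 4150 and 3880.5 genes per spot. Mitochondrial transcripts took 4.02, 4.99, 3.84 and 4.87% of all UMIs, and haemoglobin transcripts 0.272, 0.161, 0.415 and 0.137%. The labels do not say whether the sections of a group came from separate animals, so each p-value below measures the spread between sections only, which may be technical. The labels change the model and the weeks of diet together, so the contrast of MASH with MAFL is both at once.

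Cd74, H2-Ab1, Lyz2 and Tyrobp were among the genes higher in MASH than in MAFL liver. Cd74, the invariant chain of MHC class II and a receptor for MIF, rose 3.75-fold from 83.6 ± 4.17 to 314 ± 100.1 CPM (UMI counts relative to the TMM-scaled section total, mean ± SD of n = 2 sections each, log2 fold change 1.91, SE 0.24, adjusted p = 0.0338 in edgeR). The MHC class II chain H2-Ab1 rose 2.97-fold (62.8 ± 5.83 to 186 ± 49.5 CPM), the myeloid lysozyme Lyz2 3.59-fold (59.9 ± 4.27 to 215 ± 5.54 CPM) and the immune signalling adaptor Tyrobp 2.91-fold (38.5 ± 5.81 to 112 ± 17.0 CPM). The thyroxine carrier Serpina7 showed the largest increase among the genes named by the fixed rule, 6.04-fold from 7.63 ± 1.23 to 46.0 ± 10.9 CPM. The galectin Lgals1 (3.92-fold), the interferon-inducible gene Ifi27l2b (3.65-fold), the transcriptional repressor Bcl6 (3.33-fold), the actin-binding Tmsb4x (2.80-fold) and the aldehyde dehydrogenase Aldh1a7 (2.62-fold) rose as well. Only 3 decreases met the same rule: the trefoil peptide Tff3 was 3.8-fold lower in MASH (42.5 ± 10.3 to 11.2 ± 1.84 CPM), the complement component C8b 2.36-fold lower (309 ± 1.17 to 131 ± 1.92 CPM) and Alas1, the first enzyme of haem synthesis, 2.34-fold lower (757 ± 92.1 to 323 ± 3.28 CPM). In all, 62 of 13593 tested genes passed an adjusted p of 0.05 in edgeR, 42 higher and 20 lower in MASH, against 627 in DESeq2. The excess of increases was largely lost when either MAFL section was left out. The count was 20 without MAFL-1, 535 without MASH-1, 24 without MASH-2 and 0 with sections of the same number as a block (1901 genes with an unadjusted p under 0.05), and the adjusted p of Cd74 reached 0.192 over the alternatives.

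Of the other genes of the title and of the LAM and MIF field, none passed the test over whole sections. Thrsp, a nuclear regulator of lipogenesis, stood at 30.2 and 130.3 CPM in the MAFL sections and at 347 and 466 CPM in the MASH sections (log2 fold change 2.34, SE 0.80, adjusted p = 0.252), and without MAFL-2 it passed, with a log2 fold change of 3.74 (adjusted p = 0.0041, the lowest over its alternatives). Mif itself differed little, with 236 ± 15.2 CPM in MAFL and 256 ± 9.89 CPM in MASH (log2 fold change 0.12, adjusted p = 0.722). The MIF co-receptor Cd44 (log2 fold change 0.61, adjusted p = 0.185) and the chemokine receptor Cxcr4 (1.82, adjusted p = 0.139) did not pass over all genes. The LAM genes Trem2, a lipid-sensing receptor (2.20 ± 0.573 to 14.5 ± 5.94 CPM, adjusted p = 0.055), and Gpnmb, a glycoprotein of lipid-loaded macrophages (0.304 ± 0.119 to 26.0 ± 18.8 CPM, adjusted p = 0.0957), were higher in both MASH sections than in either MAFL section without passing. Trem2 passed in 4 of 13 alternatives and Gpnmb in 4 of 14, among them DESeq2 and, for both, the fit without MASH-1. Spp1, which macrophages and bile duct cells both express, had an adjusted p of 0.351 (70.3 ± 14.5 to 169 ± 122 CPM).

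**Figure D1:**
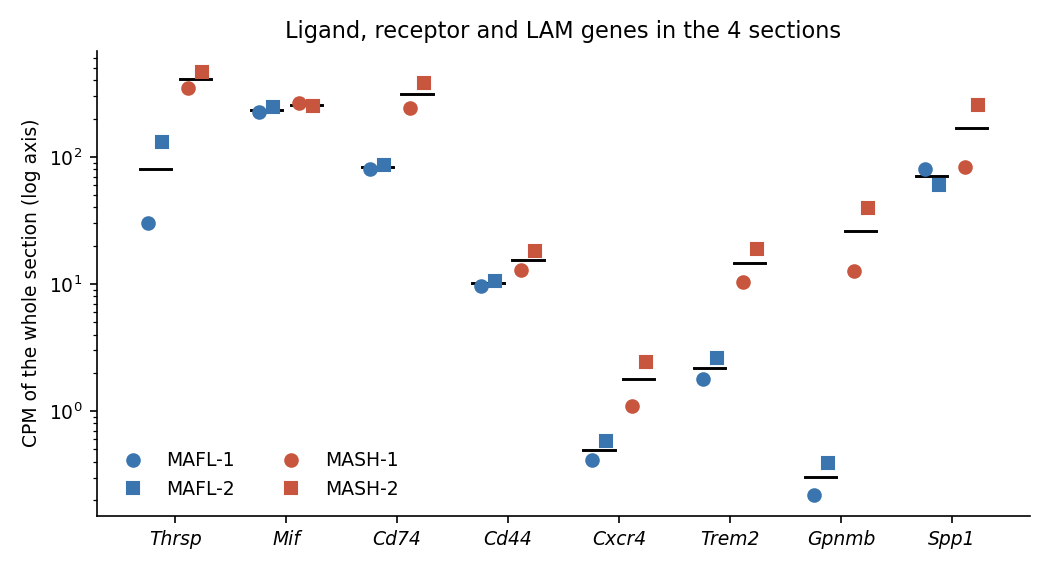
CPM of 8 genes in whole sections on a log axis. Circles are replicate 1, squares replicate 2 and black lines group means. Cd74 lay at 80.7 and 86.6 CPM in MAFL and at 243 and 384 CPM in MASH, while Mif had nearly equal group means of 236 and 256 CPM.

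Spots were also thinned to 5000 UMIs so that depth could not set the share with a transcript. Cd74 was then seen in 29.6 ± 0.0385% of MAFL spots and in 71.4 ± 10.7% of MASH spots, against 67.1 and 96.6% without thinning. Thrsp was seen in 13% (95% interval 11.6 to 14.6%) of the spots of MAFL-1, 45.9% (43.7 to 48.2%) of MAFL-2, 80.5% (78.9 to 82.1%) of MASH-1 and 90.03% (88.6 to 91.4%) of MASH-2. Mif was seen in 68.0 ± 1.08 and 72.8 ± 1.21% of thinned spots, Trem2 in 1.04 ± 0.201 and 7.33 ± 2.89%, Gpnmb in 0.208 ± 0.0108 and 10.0 ± 6.75%, and the fibrillar collagen Col1a1 in 1.98 ± 0.740 and 9.69 ± 6.06% (MAFL and MASH). The resident Kupffer cell lectin Clec4f was seen in 39.4 ± 4.65 and 46.8 ± 0.787%. Spp1 shares of the groups overlapped (22.1 ± 3.98 and 40.9 ± 23.6%). With 2 sections against 2, the smallest exact two-sided p of a rank or permutation test is 0.3333, and no test of these shares was made. The intervals cover counting error only.

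Several fixed gene lists sat higher in MASH as groups by camera, though not with an estimated correlation (lowest adjusted p = 0.668) or by fry. In the monocyte and macrophage list, 3 of 17 tested members rose over all genes (Lyz2, Tyrobp and the Fc receptor gamma chain Fcer1g, log2 fold change 1.18) and 11 rose adjusted over the list alone, with a median log2 fold change of 1.23 (camera adjusted p = 2.3e-07). Of 9 MHC class II genes, Cd74 and H2-Ab1 rose over all genes and 7 adjusted over the list alone (median 1.39, camera adjusted p = 5.7e-06). None of 12 LAM genes passed over all genes in edgeR. Adjusted over the list alone 8 rose and 1, the fatty acid binding protein Fabp5 (log2 fold change -1.35), fell (median 1.89, camera adjusted p = 5.7e-06). Fabp5, and C6 below, were chosen after their values were seen. Of 17 chemokines and cytokines, Ccl5 (log2 fold change 1.68), Cxcl9 (1.13) and Ccl6 (1.18) rose over all genes and 10 adjusted over the list alone (camera adjusted p = 2.3e-07). Ccl5 was also the only 1 of 13 T and NK cell genes to rise over all genes, with 6 adjusted over the list alone (camera adjusted p = 2.3e-06). None of 15 Kupffer genes passed over all genes, while 7 rose and 1, the complement component C6, fell adjusted over the list alone (camera adjusted p = 0.00483). With an estimated correlation between genes none of the 39 lists tested was past 0.05 (lowest adjusted p = 0.668 with an estimated correlation, the value of each list above except the Kupffer list, at 0.678), and fry called none by direction (lowest adjusted p = 0.212). The estimated correlation left no list past 0.05 in any comparison below. That includes the zones and the LAM-spot classes, where fry called 18 and 16 lists. With so few sections this setting has little power, so its values do not decide whether a list moved.

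Matrix, lipid and detoxification lists had few or no single genes past the test over all genes. None of 17 stellate cell and fibroblast genes passed over all genes and 11 rose adjusted over the list alone (camera adjusted p = 3.0e-05), and none of 25 extracellular matrix genes passed either way although 24 had a positive log2 fold change (median 0.86, camera adjusted p = 6.6e-07). In the lipogenesis list 1 of 21 genes, the acetoacetate-activating Aacs, rose over all genes (log2 fold change 1.39), 5 rose and 1 fell adjusted over the list alone, and the list was not past 0.05 (camera adjusted p = 0.112). None of 16 lipid droplet genes passed over all genes and 7 rose adjusted over the list alone (camera adjusted p = 0.00384). Of 17 xenobiotic metabolism genes, the glutathione transferases Gsta1 (0.280 ± 0.00436 to 10.0 ± 4.05 CPM) and Gstm3 (2.85 ± 0.0267 to 11.5 ± 2.33 CPM) rose over all genes and 9 adjusted over the list alone (camera adjusted p = 0.00012). All 12 genes of the male-biased liver list had a negative log2 fold change, none past the test over all genes and 4 lower adjusted over the list alone (median -0.89, camera adjusted p = 3.7e-05). Elovl3 (-0.11) and Mup20 (-0.10) lay near the shift of 0.10 that scaling by library totals gives the median gene. Each of these lists had an adjusted p of 0.668 with an estimated correlation. By camera, ribosomal protein genes (1 of 20, Rpl10, rose, camera adjusted p = 0.000257), proliferation genes (0 of 15 passed, 0.00874), p53 and injury genes (0 of 18, 3 adjusted over the list alone, 0.00546), immediate early genes (0 of 17, 5 adjusted over the list alone, 0.00483), B and plasma cell genes (0 of 10, 1 adjusted over the list alone, 0.00182) and MIF signalling genes (1 of 6, Cd74, 3 adjusted over the list alone, 0.0117) were also higher, each with an adjusted p of 0.668 with an estimated correlation.

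**Figure D2:**
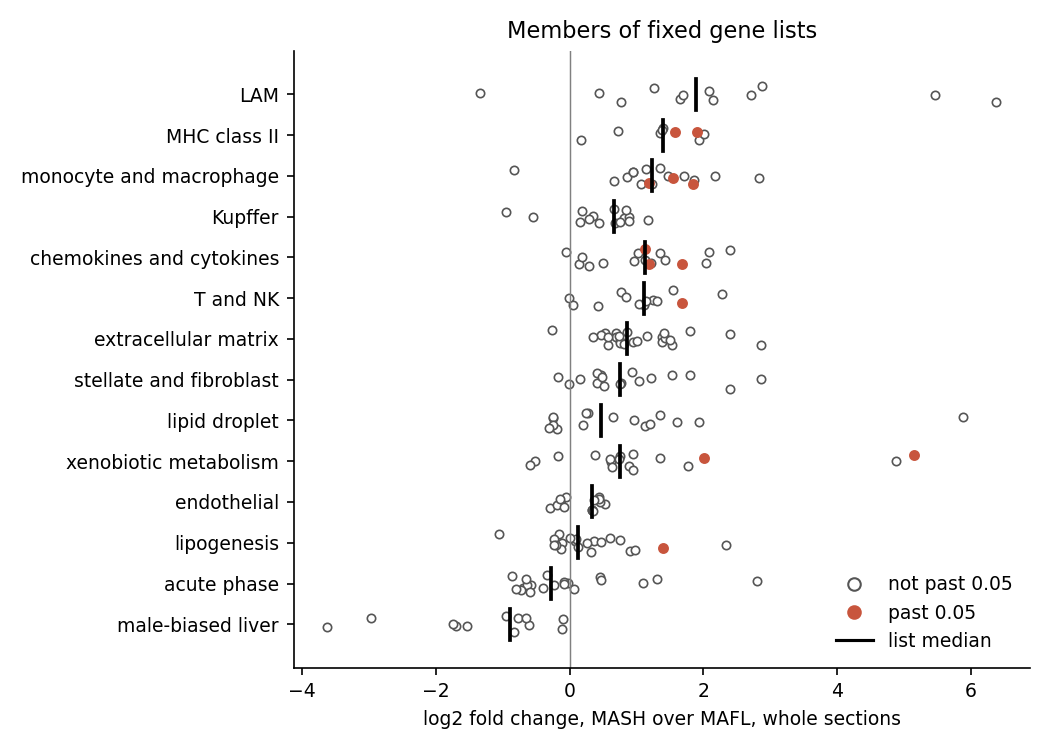
Log2 fold changes, MASH over MAFL in whole sections, of the members of 14 fixed gene lists. Filled points passed an adjusted p of 0.05 over all genes and black bars are list medians. The LAM list has the highest median, 1.89, without a filled point, and the male-biased list has a median of -0.89.

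Other lists were not past 0.05 by camera. The endothelial list held no gene past the test in either count (0 of 14, median 0.33, camera adjusted p = 0.291), nor did the cholangiocyte (0 of 8, 0.158), erythroid (0 of 6, 0.777), bile acid (0 of 14, 0.809) and lysosome (0 of 18, 0.246) lists. Oxidative phosphorylation (0 of 17, 0.24), the mitochondrial genome (0 of 13, 0.402), fatty acid oxidation and PPAR alpha targets (0 of 20, 0.278), gluconeogenesis and glycogen (0 of 12, 0.61) and hypoxia (0 of 13, 0.578) were alike. Adjusted over the list alone, 1 gene rose in each of the dendritic (camera adjusted p = 0.158), neutrophil (0.431), interferon (0.0763) and endoplasmic reticulum stress (0.158) lists, 1 gene fell in the cholesterol synthesis list (0.58), 2 fell in the circadian list (0.155), and 2 rose and 4 fell in the acute phase list (0.104). Of the female-biased list 2 genes could be tested: the cytochrome P450 Cyp2c40 fell 4.35-fold (log2 fold change -2.12, adjusted p = 0.0406) and Cyp2b9 did not pass. The 12 periportal and 18 pericentral genes that were held out of the zone score had no member past the test (camera adjusted p = 0.155 and 0.578). In the Mup family of male-typical urinary proteins, whose near-identical copies share reads, 5 of 20 tested genes fell (Mup18 20.8-fold, Mup17 15.1-fold, Mup15 13.9-fold, Mup14 3.98-fold and Mup11 24.1-fold lower), and Mup20 did not (log2 fold change -0.10, adjusted p = 0.85).

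Lobule zones were then compared within sections, taking as periportal and pericentral spots the highest and lowest tercile of a score of 6 periportal over 6 pericentral hepatocyte genes. Aldh1b1, a mitochondrial aldehyde dehydrogenase, was higher periportally. It stood at 34.4 ± 12.8 CPM in pericentral and 146 ± 44.4 CPM in periportal spots (4.30-fold). The phospholyase Etnppl stood at 21.7 ± 9.50 and 70.0 ± 24.4 CPM (3.33-fold). Spp1 (3.47-fold), the sulfurtransferase Tstd1 (3.18-fold) and Tff3 (3.12-fold) were higher periportally as well, and all 5 in 4 of 4 sections. The pericentral side was marked by the cytochrome P450 Cyp2a5 (901 ± 608 CPM pericentrally and 102 ± 67.5 CPM periportally), Cyp2c37 (6.42-fold lower periportally), Cyp2c38 (6.25-fold), the adipsin gene Cfd (7.11-fold) and the phosphatase Lhpp (7.08-fold), again in 4 of 4 sections. Of 11931 tested genes 2463 passed, 1142 higher and 1321 lower periportally, against 1213 in DESeq2. The score ranks a continuous gradient, and between 142 and 198 spots per section (7.63 to 9.23%) lay within 0.1 log2 of a tercile border.

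Among the genes of the title and of the LAM and MIF field, Cd74, Gpnmb and Cd44 were higher in periportal spots. Gpnmb was 1.75-fold higher (log2 fold change 0.81, SE 0.13, adjusted p = 3.2e-05, 4 of 4 sections), Cd44 1.28-fold (adjusted p = 0.00413, 4 of 4 sections) and Cd74 1.17-fold (log2 fold change 0.22, SE 0.06, adjusted p = 0.00254, 4 of 4 sections). The Cd74 difference was small and did not pass without MAFL-2, with a score averaging z-scores, without Cyp2f2 and Cyp2e1 in the score or with the top and bottom 20% of spots (adjusted p up to 0.0959). Within bins of total UMIs the log2 ratio of Cd74 was 0.19, 0.26 and 0.17 in MAFL-1, MAFL-2 and MASH-1 but -0.12 in MASH-2. That of Gpnmb was 1.44 in MASH-1 and 0.11 in MASH-2, while only 1 bin could be used in MAFL-1 (2.04) and in MAFL-2 (0.77), where 7 and 13 spots held a Gpnmb UMI. Mif did not pass (log2 fold change -0.05, SE 0.05, adjusted p = 0.618), nor did Trem2 (0.21, adjusted p = 0.202), Cxcr4 (0.03, adjusted p = 0.948) or Thrsp over all sections (-0.31, adjusted p = 0.253).

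Held-out zone markers followed the score, and non-hepatocyte lists differed between the zones. Of 12 held-out periportal genes 11 were higher periportally, such as the urea cycle enzyme Arg1 (1.70-fold) and the cadherin Cdh1 (3.30-fold), and Ecm1 was 1.48-fold lower. Of 18 held-out pericentral genes 17 were lower, such as Lect2 (5.44-fold). These counts were the same adjusted over the list alone. Bile duct markers were higher periportally in 6 of 7 genes in both counts (Epcam log2 fold change 1.61, Sox9 1.33, camera adjusted p = 1.7e-05, 0.286 with an estimated correlation). Of the LAM list 7 of 12 (Mmp12 1.10, Cd63 0.86, camera adjusted p = 0.0062, 0.495 with an estimated correlation) and of the monocyte and macrophage list 9 of 15 (Ms4a7 0.81, S100a4 0.74, camera adjusted p = 0.000593, 0.286 with an estimated correlation) were higher, with the same counts adjusted over the list alone. Of 15 Kupffer genes 4 were higher, led by the scavenger receptor Marco (0.80), and C6 was lower (7 and 1 adjusted over the list alone, camera adjusted p = 0.0102, 0.577 with an estimated correlation). Of 7 MHC class II genes 2 were higher, 4 adjusted over the list alone (camera adjusted p = 0.00899, 0.391 with an estimated correlation). Endothelial genes were lower periportally in 11 of 14 (Vwf -1.18, Stab1 -0.63, 13 adjusted over the list alone, camera adjusted p = 2.1e-07, 0.391 with an estimated correlation).

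Metabolic lists were divided along the same axis. Lipid droplet genes were lower periportally in 9 of 16 in both counts (Cidea log2 fold change -3.00, Fitm1 -2.01, Plin4 -1.18, camera adjusted p = 8.7e-06, 0.286 with an estimated correlation). Bile acid genes were lower in 8 of 14, with 1 higher (Cyp7a1, the rate-limiting enzyme of bile acid synthesis, -1.52, Slco1b2 -1.21, 9 and 2 adjusted over the list alone, camera adjusted p = 8.1e-05, 0.286 with an estimated correlation). All 13 mitochondrially encoded genes had negative values, 12 past the test and 13 adjusted over the list alone (mt-Nd5 -0.68, camera adjusted p = 3.9e-08, 0.391 with an estimated correlation), while 7 of 17 nuclear oxidative phosphorylation genes were higher (Cycs 0.36, 9 adjusted over the list alone, camera adjusted p = 0.000797, 0.529 with an estimated correlation). Acute phase genes were higher in 13 of 20 and lower in 1 in both counts (haemopexin Hpx 0.60, Orm3 -0.99, camera adjusted p = 0.00018, 0.529 with an estimated correlation). Lipogenesis genes went both ways, 4 higher (Acly 0.88) and 4 lower (Aacs -0.61) of 21 in both counts, as did cholesterol synthesis genes, 6 higher (Sqle 1.8) and 4 lower (Hmgcs1 -0.68) of 20 in both counts. Neither list was past 0.05 (camera adjusted p = 0.921 and 0.356). Over 37 lists, 17 passed camera, none with an estimated correlation and 18 by fry.

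The zone difference itself changed between the groups for 60 of 12502 genes by an interaction term in edgeR, 29 towards periportal and 31 towards pericentral spots in MASH. Thrsp was among them: its log2 periportal to pericentral ratio was -0.11 and 0.11 in MAFL-1 and MAFL-2 and -0.67 and -0.46 in MASH-1 and MASH-2 (interaction -0.59, SE 0.11, adjusted p = 0.00148), so it lay pericentrally in MASH. The lipid droplet fusion gene Cidec moved in the same direction, from -0.20 and -0.19 to -1.44 and -1.22 (interaction -1.13), and the nuclear long noncoding RNA Malat1 from 0.06 and -0.13 to -0.83 and -1.11 (-0.94). Lhpp (-0.96), the glutathione transferase Gstm2 (-0.71) and the transcription factor Maf (-0.63) also shifted pericentrally. The acute phase gene Saa1 moved from -0.05 and -0.48 to 0.61 and 0.71 (interaction 0.93), the antitrypsin paralogue Serpina1e from 0.55 and 0.48 to 1.61 and 1.60 (1.09), the glycine cleavage enzyme Gldc from 0.85 and 0.81 to 1.72 and 1.5 (0.80), and Lpl, which hydrolyses triglycerides, from -1.56 and -1.23 to -0.61 and -0.28 (0.93). The carboxylesterase Ces1b followed (0.78). The interaction did not pass for Cd74 (-0.07, SE 0.11, adjusted p = 0.957), Mif (0.05, SE 0.10, adjusted p = 0.977), Trem2 (0.62, adjusted p = 0.719), Gpnmb (-0.67, adjusted p = 0.946) or Spp1 (0.19, adjusted p = 0.881). The count was 20 in DESeq2, 17 without MAFL-2, 365 without MASH-1, 227 without MASH-2, 36 with z-scores and 26 without Cyp2f2 and Cyp2e1. For Thrsp the adjusted p was 0.896 without MAFL-2 and 0.062 without Cyp2f2 and Cyp2e1 (interaction -0.47 and -0.51).

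Lists moved modestly under this interaction. All 20 acute phase genes and all 20 ribosomal protein genes had positive values, with 1 (Saa1) and 0 past the test in both counts (camera adjusted p = 2.1e-05 for each). The smallest, Steap4 (0.04) and Rpl19 (0.05), lay within the shift of -0.06 under scaling by library totals. Of 18 held-out pericentral genes 2 had a more pericentral ratio in MASH and 9 adjusted over the list alone (camera adjusted p = 5.1e-05), and of 12 held-out periportal genes 2 had a more periportal ratio, Gldc and Etnppl (0.62), with 5 up and 1 down adjusted over the list alone (camera adjusted p = 0.00389). In the lipogenesis list Thrsp and the sterol response factor Srebf1 (-0.44) were past the test, 3 of 21 adjusted over the list alone, and the list was not (camera adjusted p = 0.568). Each of these lists had an adjusted p of at least 0.717 with an estimated correlation. The deeper counts of periportal spots were uneven between groups: median UMIs per spot were 15704 periportally and 15528 pericentrally in MAFL-1, 22465 and 17720 in MAFL-2, 33082.5 and 20633.5 in MASH-1 and 34111 and 15369 in MASH-2.

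**Figure D3:**
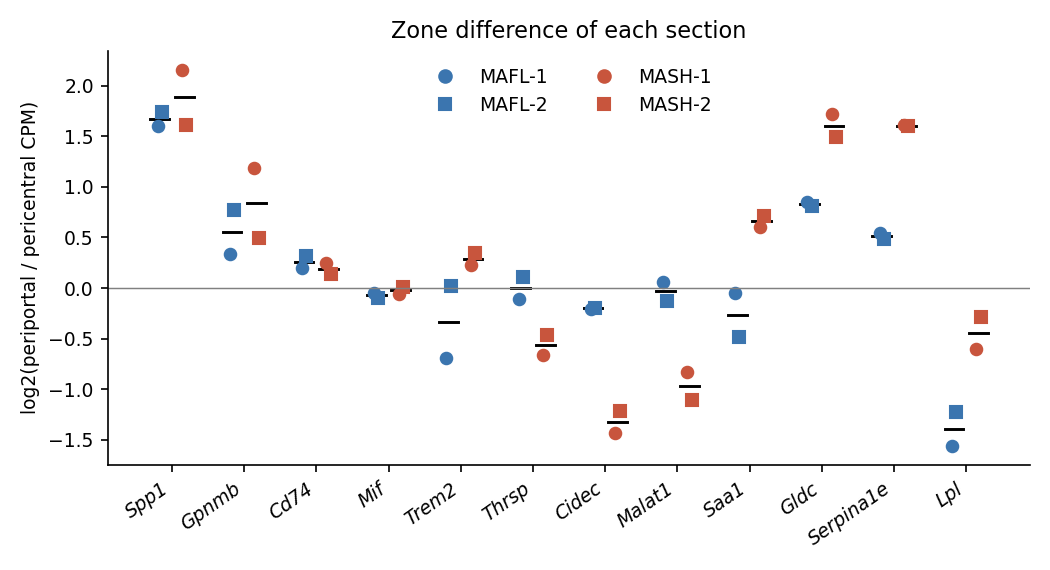
Log2 ratio of periportal to pericentral CPM per section for 12 genes. Values above 0 are higher periportally. Thrsp, Cidec and Malat1 lie lower in both MASH sections than in both MAFL sections, Saa1, Gldc, Serpina1e and Lpl lie higher, and Mif lies near 0 in all 4 sections.

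Within each zone Cd74, Trem2, H2-Eb1 and Lgals1 stood higher in MASH. In periportal spots Cd74 was 3.8-fold higher in MASH (86.9 ± 8.80 to 331 ± 100.1 CPM, adjusted p = 0.0184), Trem2 8.64-fold (1.87 ± 0.948 to 16.7 ± 6.41 CPM, adjusted p = 0.0485), the macrophage elastase Mmp12 48.6-fold (0.803 ± 0.0944 to 39.7 ± 21.2 CPM), the galectin Lgals3 4.41-fold and Lyz2 4.28-fold. The fatty acid transporter Cd36 was 2.65-fold higher. Lgals1 (3.99-fold) and H2-Eb1 (3.88-fold) rose too, and Tff3 (3.78-fold), Alas1 (2.98-fold), the carboxylesterase Ces3b (2.26-fold), C8b (2.08-fold) and the helicase Ddx17 (2.08-fold) were lower. In pericentral spots Cd74 was 4.05-fold higher (73.8 ± 2.66 to 299 ± 107 CPM, adjusted p = 0.012), Trem2 5.64-fold (adjusted p = 0.00702), Serpina7 5.80-fold, H2-Eb1 4.36-fold, H2-Aa 4.27-fold and Lgals1 3.89-fold, while C8b (2.86-fold), the small membrane protein Smim22 (2.79-fold), the asparaginase Aspg (2.5-fold), Ces3b (2.40-fold) and the prostaglandin transporter Slco2a1 (2.25-fold) were lower. Thrsp (adjusted p = 0.407 and 0.256), Mif (0.648 and 0.774) and Gpnmb (0.0579 and 0.174) did not pass in the periportal and pericentral comparisons. The periportal comparison gave 110 of 12500 genes (82 higher, 28 lower in MASH) and the pericentral one 107 of 11792 (67 higher, 40 lower). The interaction above is the test of their difference. Without MAFL-1, MAFL-2, MASH-1 and MASH-2 the periportal count was 14 (7 higher, 7 lower), 22 (6 higher, 16 lower), 496 and 63. The excess of increases was thus lost without either MAFL section, and the pericentral excess was then lost or nearly so as well. Without MAFL-1 and MASH-1 the pericentral count was 50 (23 higher, 27 lower) and 895. Sections of the same number as a block gave 82 and 52, and the adjusted p of Cd74 reached 0.135 and 0.0527, and that of periportal Trem2 0.167, over the alternatives.

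By lists, 5 of 9 MHC class II genes rose in periportal spots (7 adjusted over the list alone) and 5 of 7 in pericentral spots (7 adjusted over the list alone, camera adjusted p = 1.6e-06 and 1.0e-07). The monocyte and macrophage list had 6 of 17 and 4 of 15 genes higher (11 and 9 adjusted over the list alone, camera adjusted p = 3.4e-08 and 7.9e-09), among them Ms4a7 with log2 fold changes of 2.70 and 3.05. Of 12 LAM genes 3 rose periportally (Mmp12, Lgals3 and Trem2) and 2 pericentrally (Trem2 and the actin-capping Capg, 1.38), with 10 and 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 7.0e-08 and 2.0e-05). Chemokines rose in 4 of 15 and 4 of 13 (9 and 7 adjusted over the list alone, camera adjusted p = 6.6e-09 and 6.0e-07). Collagen Col3a1 was the only 1 of 24 extracellular matrix genes past the test pericentrally (log2 fold change 1.59), none of 25 was periportally, and 16 and 12 rose adjusted over the list alone (camera adjusted p = 1.7e-08 and 3.4e-08). In all, 17 of 39 lists passed camera in periportal and 24 of 39 in pericentral spots. With an estimated correlation the lowest adjusted p was 0.595 and 0.569, and fry called no list in either zone (lowest adjusted p = 0.152 and 0.156).

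Spots rich in LAM genes were compared with poor ones in the same section, taking the top 10% and the bottom 50% of the share of 13 LAM genes, which were left out of the test. Cd74, Gsn and Col1a1 were among the genes higher in the LAM-gene-high spots. Cd74 was 2.08-fold higher (168 ± 114 to 357 ± 265 CPM, log2 fold change 1.06, SE 0.06, adjusted p = 1.6e-13, 4 of 4 sections), the actin-severing Gsn 4.33-fold (32.6 ± 15.4 to 136 ± 30.1 CPM), Col1a1 3.67-fold (8.19 ± 6.90 to 32.9 ± 38.5 CPM), S100a6 3.47-fold, the immunoglobulin heavy chain Igha 3.20-fold and the extracellular glutathione peroxidase Gpx3 3.18-fold. Cfd (2.17-fold), Cyp2e1 (1.92-fold), the steroid dehydrogenase Hsd3b5 (1.87-fold), the hepatokine Lect2 (1.82-fold) and Fitm1 (1.78-fold) were lower, each in 4 of 4 sections. Cd44 was 1.53-fold (adjusted p = 0.000207) and Cxcr4 2.41-fold higher (adjusted p = 0.00648), whereas Mif (log2 fold change -0.03, SE 0.06, adjusted p = 0.755) and Thrsp (-0.04, adjusted p = 0.879) did not pass. In all 2427 of 11889 genes passed, 1215 higher and 1212 lower, against 1073 in DESeq2, 1329 without MASH-1 and 1483 without MASH-2. The balance of directions depended on the scale and filter, with 1994 higher and 335 lower under library totals alone and 1379 higher and 2016 lower without a low-count filter. The list decided much of this: without Spp1, Cd63 and Cd9, which bile duct cells also express, 178 genes passed, 168 higher and 10 lower (161 of them shared), and Cd74 (log2 fold change 0.82, adjusted p = 0.22), Col1a1 (1.44), Gsn (0.40), Epcam (0.61) and Cyp2e1 (-0.11) did not. The fit over all zones did not hold zone fixed. In periportal spots alone 1701 genes passed, 916 higher and 785 lower, 1398 of them shared with the fit over all zones. The high spots held a median of only 9, 8, 22 and 36 LAM UMIs in MAFL-1, MAFL-2, MASH-1 and MASH-2, against 2, 2, 3 and 6 in the low spots.

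Every MHC class II gene tested was higher in LAM-gene-high spots, 8 of 8 in both counts (H2-Eb1 2.37-fold, camera adjusted p = 2.7e-09). With an estimated correlation this list and each other list of this paragraph that camera called had an adjusted p of 0.364. The monocyte and macrophage list had 11 of 15 higher in both counts (S100a4 4.40-fold, the chemokine receptor Ccr2 3.56-fold, camera adjusted p = 8.7e-10). Extracellular matrix genes were higher in 19 of 25, 22 adjusted over the list alone (the protease inhibitor Timp1 5.21-fold, Col6a3 3.08-fold, camera adjusted p = 1.3e-13), and stellate cell and fibroblast genes in 10 of 16, 13 adjusted over the list alone (camera adjusted p = 4.2e-07). Cholangiocyte genes were higher in 6 of 7, 7 adjusted over the list alone (Epcam 7.36-fold, Krt19 6.44-fold, Krt7 5.06-fold, camera adjusted p = 8.6e-09), and T and NK genes in 6 of 9, 7 adjusted over the list alone (camera adjusted p = 6.5e-05). Of 15 Kupffer genes only C1qa was higher and C6 lower, in both counts (camera adjusted p = 0.867). Bile acid genes were lower in 10 of 14, 14 adjusted over the list alone (camera adjusted p = 7.9e-07), fatty acid oxidation genes in 12 of 20, with 14 lower and 1 higher adjusted over the list alone (camera adjusted p = 9.3e-05), and mitochondrially encoded genes in 12 of 13 in both counts (camera adjusted p = 4.2e-07). Held-out pericentral genes were lower in 8 of 18, 16 adjusted over the list alone (camera adjusted p = 7.8e-08). Bile acid, mitochondrially encoded and held-out pericentral genes were also lower in periportal spots. Median zone scores were higher in LAM-gene-high than in low spots of every section. Zone was not held fixed in these list tests, so the lower values cannot be told apart from zone. Spp1 belongs to the cholangiocyte list and bile duct cells also express Cd63 and Cd9. The class thus draws in bile duct spots, and the cholangiocyte counts follow in part from its definition. Without these 3 genes, and over the genes tested both ways, 1 of 7 MHC class II, 5 of 15 monocyte and macrophage, 10 of 25 extracellular matrix, 3 of 16 stellate cell and fibroblast, 0 of 6 cholangiocyte and 1 of 8 T and NK genes were higher over all genes. Adjusted over the list alone these counts were 7, 9, 19, 12, 1 and 3, and the median log2 fold changes were 0.73, 0.95, 0.76, 0.50, 0.24 and 0.66. All 7, 15 and 16 MHC class II, monocyte and macrophage, and stellate cell and fibroblast genes stayed positive. None of the bile acid, fatty acid oxidation, mitochondrially encoded and held-out pericentral genes was then lower over all genes (0, 1, 11 and 0 adjusted over the list alone). Over 38 lists 24 passed camera and 16 fry.

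What shared spots with LAM genes differed between the groups for 135 of 12617 genes by the interaction term, 61 towards a higher and 74 towards a lower ratio in MASH. Cd68 and Ccl6 followed the LAM list more closely in MASH: the log2 ratio of high to low spots of Cd68 was -0.05 and 0.02 in MAFL-1 and MAFL-2 and 1.21 and 1.51 in MASH-1 and MASH-2 (interaction 1.4), and that of the chemokine Ccl6 was -0.06 and -0.04 against 1.17 and 1.16 (1.23). The acute phase genes Saa2 (1.64) and Saa1 (1.32) and the immunoglobulin light chain Igkc (1.78) moved the same way. The glutamate transporter Slc1a2 (-1.09), the fatty acid elongase Elovl3 (-1.05), Lhpp (-1.01), Cyp2c37 (-0.98) and the ubiquitin ligase Mkrn1 (-0.92) moved the other way. Thrsp was higher in LAM-gene-high spots of MAFL-1 and MAFL-2 (0.35 and 0.29) and lower in those of MASH-1 and MASH-2 (-0.30 and -0.31, interaction -0.61, SE 0.11, adjusted p = 0.000214). The high spots held a median of 9 and 8 LAM UMIs in MAFL-1 and MAFL-2, against 22 and 36 in MASH-1 and MASH-2. The class thus rested on fewer UMIs in MAFL. A ratio near 0 there does not show that a gene lies apart from macrophages. Zone was not held fixed here. Median zone scores of high and low spots were 1.43 and 0.526 in MAFL-1 and 0.585 and -0.737 in MAFL-2. In MASH-1 they were 0.935 and -2.02 and in MASH-2 0.181 and -1.30. Over all thinned spots the Spearman correlation of Thrsp with the LAM list was 0.0615 in MAFL-1, 0.0586 in MAFL-2, -0.026 in MASH-1 and 0.056 in MASH-2. By this measure the sign changed in MASH-1 and not in MASH-2. Within periportal spots of MASH-1 and MASH-2 this correlation was 0.0273 and 0.166. It was 0.0544 and 0.0707 in middle and -0.0252 and 0.0476 in pericentral spots. The change of sign of the Thrsp ratio between high and low spots cannot be told apart from zone. The interaction of Cd74 (-0.01, SE 0.11, adjusted p = 0.995) and Mif (0.06, adjusted p = 0.928) did not pass. The count was 53 in DESeq2, 48 without MAFL-1, 18 without MAFL-2, 368 without MASH-1, 366 without MASH-2, 110 (66 higher, 44 lower) with library totals alone and 385 without Spp1, Cd63 and Cd9 in the list. The adjusted p of Thrsp was 0.106 without MAFL-1 and 0.259 without MAFL-2, Mkrn1 reversed (0.15) without the 3 genes, and Cd74 then had an interaction of 0.74.

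In the lists, 5 of 15 Kupffer genes (Cd5l 0.71, C1qc 0.67, C1qb 0.63), 5 of 16 monocyte and macrophage genes (Ctss 0.83, Mpeg1 0.69) and 5 of 18 lysosome genes (the protease Ctsd 0.55) had a higher ratio in MASH, with 6, 7 and 9 higher and 1, 1 and 0 lower adjusted over the list alone (camera adjusted p = 0.00862, 0.000383 and 0.000337). Of 20 acute phase genes 4 were higher, Orm2 (1.0) and Lcn2 (1.19) among them, and 1 lower (7 and 2 adjusted over the list alone, camera adjusted p = 0.0179). Held-out pericentral genes had a lower ratio in 9 of 18 (15 adjusted over the list alone, camera adjusted p = 3.3e-13), bile acid genes in 5 of 14 (11 adjusted over the list alone, camera adjusted p = 1.0e-05) and male-biased genes in 7 of 12 (9 adjusted over the list alone, camera adjusted p = 1.0e-05). Each had an adjusted p of 0.631 with an estimated correlation. The xenobiotic list had a mean of 0.11 and a median of -0.19, with a test towards lower values (3 of 16 lower, 4 adjusted over the list alone, camera adjusted p = 0.0334, 0.631 with an estimated correlation).

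LAM-gene-high spots were more often periportal than pericentral in every section. The periportal share was 48.3% (95% interval 41.5 to 55.1%) in MAFL-1, 53.2% (46.1 to 60.1%) in MAFL-2, 78.0% (72.4 to 82.7%) in MASH-1 and 52.4% (45.3 to 59.5%) in MASH-2, and the pericentral share 14.6, 21.1, 11 and 13%. The group means of the periportal share were 50.7 ± 3.44% and 65.2 ± 18.1% (n = 2 each), and their difference lay within the spread of the MASH sections. Without Spp1, Cd63 and Cd9 in the list, the order turned in MAFL: the periportal share was 25.4 and 23.7% and the pericentral share 42.9 and 45.3%, whereas in MASH they were 47.8 and 39.5% against 26.1 and 21.1%. Without Lpl as well, a list chosen after the data were seen, the mean periportal and pericentral shares were 30.4 and 31.9% in MAFL and 45.2 and 21.4% in MASH, and the pericentral excess in MAFL was no longer seen. The classes are ranges of a score and not cell types.

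**Figure D4:**
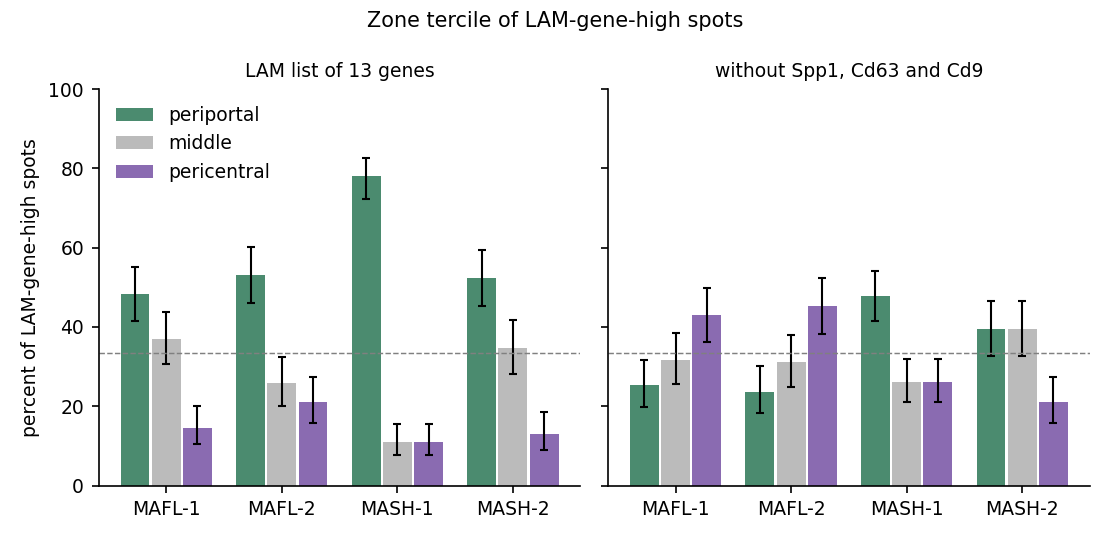
Percent of LAM-gene-high spots in each zone tercile per section with 95% Wilson intervals, with the 13-gene list (left) and without Spp1, Cd63 and Cd9 (right). The dashed line is the share expected from equal classes. On the right, the periportal share lies below the pericentral share in both MAFL sections (25.4 and 23.7%) and above it in both MASH sections (47.8 and 39.5%).

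Few genes passed between spots with a high and a low Thrsp share. Serpina7 was 1.65-fold higher in Thrsp-high spots (21.0 ± 17.4 to 34.7 ± 31.6 CPM), the lipid droplet gene Cidea 1.92-fold (11.3 ± 16.1 to 21.6 ± 31.9 CPM, 3 of 4 sections), the tropomyosin Tpm2 1.35-fold, Slc1a2 1.31-fold, Gstm2 1.30-fold, Lgals1 1.25-fold and the ketogenic and sterol enzyme Hmgcs1 1.22-fold. Mmp12 was 1.88-fold lower (3 of 4 sections), and Cd52 (1.24-fold), Ces1b (1.22-fold), the haem oxygenase Hmox1 (1.21-fold), Mpeg1 (1.14-fold) and Fgl1 (1.11-fold) were lower in 4 of 4 sections. Mif (log2 fold change 0.04, SE 0.03, adjusted p = 0.769) and Cd74 (-0.01, SE 0.04, adjusted p = 0.979) did not pass, and none of the 20 other lipogenesis genes passed in either count (camera adjusted p = 0.149). In the lipid droplet list 1 of 16 rose (5 adjusted over the list alone, camera adjusted p = 6.1e-05), in the Kupffer list 1 of 15 fell (11 fell and 1 rose adjusted over the list alone, camera adjusted p = 6.1e-05) and in the acute phase list 1 of 20, Lcn2, fell (11 adjusted over the list alone, camera adjusted p = 4.4e-06), each with an adjusted p of 0.822 with an estimated correlation. In all 35 of 12043 genes passed, 20 higher and 15 lower, against 4 in DESeq2, 72 (30 higher, 42 lower) without MAFL-1, 86 without MAFL-2, 8 without MASH-1, 6 without MASH-2, 7 with a mean CPM of at least 10, 13 with ranks taken without bins of total UMIs and 107 (30 higher, 77 lower) when ranked within zones. Ranked within zones, Slc1a2, itself a pericentral gene of the zone score, changed sign (log2 fold change -0.05, adjusted p = 0.849), and Serpina7 (0.19, adjusted p = 0.0511), Tpm2 (0.11), Gstm2 (0.06) and Hmgcs1 (0.12) did not pass. The split was coarse in MAFL-1, where Thrsp-high spots held a median of 1 Thrsp UMI and low spots 0. Only 35.4% of the spots of MAFL-1 held a Thrsp UMI, and ties were broken at random. The medians were 4 and 1 in MAFL-2, 13 and 5 in MASH-1 and 16 and 6 in MASH-2. Classes from the counts of 1 gene are blurred by counting error. Genes that did not pass may thus still vary with Thrsp.

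Thrsp-high spots lay pericentrally in MASH. In MASH-1 47.4% (95% interval 44.1 to 50.9%) of them were pericentral and 20.1% (17.5 to 22.9%) periportal, and in MASH-2 46.1% (42.2 to 50.1%) and 24.2% (21.0 to 27.7%). In MAFL-1 the shares were 36.8 and 33.5%, and in MAFL-2 35.1 and 38.5%, with overlapping intervals in both.

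Across the thinned spots of a section, the genes of the title and the LAM list were weakly correlated. These spots held few UMIs of each gene. The section means ran from 0.144 to 2.63 for Thrsp, from 0.400 to 2.02 for Cd74 and from 1.13 to 1.35 for Mif. Counting error at such numbers draws a correlation towards 0, so weak values do not show that these genes lie apart. Spearman's rho of Thrsp with the LAM list had a mean of 0.0375 over the 4 sections (range -0.026 to 0.0615), Mif with Cd74 0.0175 (-0.018 to 0.0361), Mif with the LAM list 0.0313 (0.0171 to 0.053), Thrsp with Mif 0.014 and Thrsp with Cd74 -0.00696. Cd74 with the LAM list gave 0.105 (0.0184 to 0.214). Within periportal spots Thrsp with the LAM list had a mean of 0.0673 (0.0152 to 0.166, the highest in MASH-2). Within middle spots this correlation ran from 0.0544 (MASH-1) to 0.0870 (MAFL-1) and within pericentral spots from -0.0252 (MASH-1) to 0.0928 (MAFL-1). The periportal values thus did not stand apart as a set. Of 200 genes of matched abundance, 2, 41, 2 and 0 correlated with the LAM list as highly as Cd74 in MAFL-1, MAFL-2, MASH-1 and MASH-2, against 5, 4, 144 and 65 for Thrsp and 41, 13, 54 and 23 for Mif. Spots of a section are neighbours and not independent replicates, so each section gives 1 value and no test was made across sections.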

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

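The tests of the zone score and of the lipogenesis median for Thrsp, of the endothelial list and of thinning for the LAM genes, of the LAM list without Spp1, Cd63 and Cd9 and without Lpl as well, and of flipped class labels were chosen only after the result was seen. The bounds for the zone score, for Thrsp within bins of UMIs and for the list without Lpl were written after the patterns had been seen and before the values of these 3 tests. The zone difference of 60 genes differed between MASH and MAFL by the interaction term, which is what set them apart here. Among the 29 towards periportal spots in MASH were Serpina1e (interaction 1.09 log2), Lpl (0.93), Saa1 (0.93), Gldc (0.797) and Ces1b (0.78). Among the 31 towards pericentral spots were Cidec (-1.13), Lhpp (-0.96), Malat1 (-0.94), Gstm2 (-0.71), Maf (-0.63) and Thrsp (-0.59). The difference between LAM-gene-high and LAM-gene-low spots differed between the groups for 135 genes by the same kind of term. Among the 61 towards higher ratios in MASH were Igkc (1.78), Saa2 (1.64), Cd68 (1.4), Saa1 (1.32) and Ccl6 (1.23). Among the 74 towards lower ratios were Slc1a2 (-1.09), Elovl3 (-1.05), Lhpp (-1.01), Cyp2c37 (-0.98), Mkrn1 (-0.92) and Thrsp (-0.61).

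Thrsp lay pericentrally in both MASH sections, and weakly in MAFL-1 and not in MAFL-2. Within 5 bins of total UMIs per section the difference between the groups was -0.683 log2 (sections -0.06, 0.09, -0.63 and -0.71). This argues against the deeper periportal spots of MASH as its source, as far as such bins hold depth fixed. Each bin holds an equal share of spots and still spans a range of UMIs. Without Cyp2f2 and Cyp2e1 in the score the fitted difference was -0.508 (SE 0.112) against -0.59 (SE 0.11) with them. The call ended (adjusted p = 0.062) with a smaller difference at an equal spread, while both MASH sections stayed below both MAFL sections (-0.07, 0.04, -0.62 and -0.54). The median interaction of the 20 other lipogenesis genes was 0.03 (95% bootstrap interval -0.101 to 0.09), far from the Thrsp value, which argues against a shift of the whole lipogenesis list. This interval also concerns a median over genes and not the spread between sections. A different response of Thrsp to the longer diet or the model may remain, as may a difference between single sections, since the call was lost without MAFL-2 (interaction -0.47), and neither was tested.

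LAM genes sat higher in MASH sections as a list by camera, without a single member past the test in edgeR, and the list was not past it with an estimated correlation (adjusted p = 0.668) or by fry (0 lists). The LAM median exceeded the endothelial median by 1.557 log2 (95% bootstrap interval 0.821 to 2.733). This argues against a lower share of hepatocytes alone, since that would raise all other cell types alike, provided endothelial RNA did not itself fall. The interval concerns medians over list members and does not cover the spread between sections. At 1 depth of 5000 UMIs the log2 ratio of LAM UMIs per spot was 1.065, against 1.671 without thinning, and it met neither bound set for this test. UMIs per spot rise with depth, so a fall on thinning was fixed in advance. It says nothing about the camera result, which rests on CPM already scaled for depth. The LAM genes together stood at 248, 179, 291 and 692 CPM of the section total in MAFL-1, MAFL-2, MASH-1 and MASH-2. LAM UMIs per thinned spot were 1.35, 0.942, 1.48 and 3.31 in the same order, so most of the ratio at 1 depth comes from MASH-2. Spp1 of this list, which bile duct cells also express, had 0.438, 0.288, 0.416 and 1.25 UMIs per spot at the same depth in these sections. More macrophages, a change in the macrophages present, RNA of bile duct cells and a difference between single sections could each add to these values. The sections do not separate them.

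LAM-gene-high spots lay periportally in both groups with the fixed list. Without Spp1, Cd63 and Cd9, genes that bile duct cells also express, the periportal minus pericentral share in MAFL was -19.6 percentage points (95% intervals -28.6 to -6.51 and -33.0 to -10.2 in MAFL-1 and MAFL-2), so in MAFL the periportal excess depended on these 3 genes. Spp1 and Cd63 were themselves higher periportally, so leaving them out lowers the share whichever cells express them. Bile duct RNA could be the source, but this test cannot show it. Without Lpl as well, a list member that lay pericentrally in MAFL, the difference was -1.44 points (-14.2 to 7.35 and -10.7 to 11.8), so no periportal excess was left, and it stays open whether Lpl alone gave the pericentral one, as the intervals span 0. With the full list the high spots of MAFL-1 and MAFL-2 held a median of 9 and 8 LAM UMIs. Shorter lists rank spots on fewer UMIs, and counting error draws the zone shares together. In MASH the difference without the 3 genes was 20.01 points (11.2 to 32 and 7.48 to 29.3) and without Lpl as well 27.8 and 20 points, which argues against these genes as its only source there. Whether the remaining MASH excess reflects a periportal position of macrophages may be settled only with a cell-level measurement, as the remaining genes are also expressed by other cells.

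The class labels could be flipped within the sections in 8 ways, too few for a share under 0.05. The real labels, counted as 1 of the 8, gave 2463 zone genes, with 1 gene as the highest of the others. They gave 2427 LAM-spot genes, with 0 as the highest of the others, and 35 Thrsp-spot genes, with 22 as the highest of the others.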

How the results depend on the processing

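The 8 alternatives chosen after the data were seen were the crossed pairing, the 3 other zone scores or classes for the zone interaction the LAM list without Spp1, Cd63 and Cd9 for the LAM interaction and the zones of LAM-gene-high spots, and for these zones the list without Lpl and without all 4 genes. Among the 425 named gene results past the threshold, 5206 values under an alternative kept direction and call, 938 kept the direction without the call and 8 reversed. Leaving out a section leaves 1 section in an arm, which is then assumed to vary like the others. The wide ranges below set the limit on the group contrasts: with 2 sections per group, the number of genes past the threshold is not settled. Directions of the named genes seldom changed, but their choice largely fixed this. All had passed the threshold, and those of the fixed rule had the same direction in every section. Few reversals thus do not show that directions are stable. Low depth of Thrsp in MAFL-1, with a median of 1 UMI in Thrsp-high spots, and of LAM genes, with 9 and 8 UMIs in the high spots of MAFL-1 and MAFL-2, limits the spot classes. The cause was not tested.

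With DESeq2 the counts were 627 genes for whole sections, 1213 for zones, 20 for the zone interaction, 357 in periportal and 273 in pericentral spots, 1073 for LAM spots, 4 for Thrsp spots and 53 for the LAM interaction. Without a low-count filter they were 1153 for whole sections, 1197 periportally, 1066 pericentrally and 177 for Thrsp spots; with a mean of at least 10 CPM they were 20, 69, 26 and 7, and 947 for LAM spots. Library totals gave 43 genes pericentrally. The zone interaction gave 36 genes with z-scores and 26 without Cyp2f2 and Cyp2e1. Without Spp1, Cd63 and Cd9 the LAM spots gave 178 genes, the LAM interaction 385, and the periportal share of LAM-gene-high spots was 24.5% in MAFL and 43.6% in MASH, or 30.4 and 45.2% without Lpl as well and 55.1 and 66.8% without Lpl alone; the MAFL share was 58.6% with the top 5% and 45.2% with z-scores. Thrsp spots gave 13 genes without bins and 107 ranked within zones. An estimated correlation left 0 lists past the threshold in camera, against 17 with the preset one and 0 by fry. The Cd74 share differed by 29.5 points without thinning and 18.5 points at 1000 UMIs, against 41.8.

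With sections of the same number as a block, 0 genes passed for whole sections in edgeR (1901 with an unadjusted p under 0.05) and 52 pericentrally. Same-numbered sections deviated in opposite directions (correlation across genes -0.195; genes are not independent replicates), and the crossed block gave 781 genes.

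Leaving out 1 section gave 20 to 535 genes for whole sections, 1649 to 2173 for zones, 17 to 365 for the zone interaction, 14 to 496 periportally, 50 to 895 pericentrally, 1329 to 2395 for LAM spots, 6 to 86 for Thrsp spots, 18 to 368 for the LAM interaction and 18 to 21 lists. The highest counts came without MASH-1 for the group contrasts and the interactions, and the lowest without MAFL-1 or, for the interactions, MAFL-2, while each of the 4 sections moved the Thrsp count by more than 1.5 times. The Cd74 share then differed by 34.2 to 49.4 points, the periportal share of LAM-gene-high spots was 48.3 to 53.2% in MAFL and 52.4 to 78.0% in MASH, and the mean correlation was 0.0295 to 0.0587 for Thrsp with the LAM list and 0.0113 to 0.0293 for Mif with Cd74.

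The reversals were S100a6 between zones without Cyp2f2 and Cyp2e1 (-0.01); in LAM spots without Spp1, Cd63 and Cd9 Hsd17b13 (-0.108, and -0.123 in periportal spots alone), Ecm1 (0.093), Slc13a3 (0.099) and Acly (-0.124); Mkrn1 in the LAM interaction with the same list (0.147); and Slc1a2 in Thrsp spots ranked within zones (-0.048).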

Other observations

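Thrsp stood apart from other lipogenesis genes in the MAFL sections. The log2 ratio of MAFL-2 to MAFL-1 was 2.11 for Thrsp, and those of the 20 others ranged from -0.44 (Me1) to 0.62 (Acss2) with a median of 0.09. MAFL-1 held 30.2 and MAFL-2 130.3 CPM of Thrsp, while Fasn lay at 61.4 and 66.7 CPM, Acly at 67.8 and 72.3 CPM and Scd1 at 7953 and 8606 CPM in the same sections. In MASH-1 and MASH-2 Fasn lay at 80.2 and 84.8 CPM, Acly at 63.7 and 62.1 CPM and Scd1 at 9396 and 5919 CPM, and none of the 3 passed between the groups (adjusted p = 0.252, 0.597 and 0.837). These genes were chosen after their values were seen.

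Several genes with large differences between the groups did not pass, with the sections of a group far apart, and they too were chosen after their values were seen. The lipid droplet gene Cidea stood at 0.63 and 0.444 CPM in MAFL-1 and MAFL-2 and at 50.2 and 12.7 CPM in MASH-1 and MASH-2 (adjusted p = 0.135). The adipsin gene Cfd stood at 6.55, 45.4, 389 and 24.1 CPM (adjusted p = 0.448), the iron-binding acute phase gene Lcn2 at 9.63, 12, 38.2 and 112.8 CPM (adjusted p = 0.156) and Serpina1e at 7668, 3247, 965 and 431 CPM (adjusted p = 0.136), in the same order of sections. The male-biased genes Cyp7b1 (374, 175.6, 103.4 and 65.8 CPM) and Selenbp2 (314, 161.5, 53.8 and 88.5 CPM) were lower in both MASH sections without passing (adjusted p = 0.156 and 0.139).

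In log2 CPM of all tested genes the first principal component held 62.6% of the variance and placed MAFL-1 and MAFL-2 at -34.4 and -29.9 and MASH-1 and MASH-2 at 15.4 and 48.8. The remaining components held 23.9 and 13.5%.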
